A study of Homo sapiens with 12 samples.

How the data were processed

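RNA from 12 cultures of MCF10-A cells was analysed. Per the labels' protocols, wells received 150000 cells, induction with 50 ng/ml doxycycline began 20 hours later, and DMSO or 100 nM Torin2 followed 24 hours after that. Medium was changed at intervals of 48 hours until collection at day 5. Messenger RNA was selected with oligo-dT beads and made into libraries with a strand-keeping KAPA kit, per the labels' protocols.

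The authors deposited a file of counts for each library. Per the file headers, reads were assigned to exons with featureCounts 1.6.3, summarised by gene name over the GENCODE 29 annotation, with no option set for strand, multimapping reads or read pairs. HISAT2, Subread, FastQC 0.11.3, DESeq2 and the genome build GRCh38.p7 are named in the submitters' processing notes. As strand was not used, reads from overlapping genes on either strand cannot be told apart, and without such an option featureCounts leaves reads that overlap several genes unassigned. Of 1055 genes in the lists, 21 had over 50% and 58 over 30% of their exonic bases shared with another gene.

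The authors also deposited 3 tables of comparisons (p16 and p21 over mVenus, and p16 with Torin2 over p16), each of 19758 genes. In them the authors give a log2 fold change with its standard error, a p-value with its adjusted value, a statistic (a score per gene) and a mean signal per gene over libraries. These tables were used only as a check. Own DESeq2 log2 fold changes had r = 1 across genes with those of each table, but it is not known whether the tables rest on the deposited counts. The authors' deposited tables hold 4446 higher and 4317 lower genes for p16, 3896 and 3665 for p21, and 3771 and 4124 for Torin2 at an adjusted p under 0.05. In the authors' deposited table MKI67 has a log2 fold change of -5.02 in p16, -6.61 in p21 and 2.34 with Torin2. The ratio of the authors' mean to the mean of the counts after own size factors had a median of 0.988 (quartiles 0.940 and 1.04) among genes with an authors' mean of at least 10. Among names in the p16 comparison, 23 did not match the count files and 2 were repeated, and 5 listed genes had 0 counts in all 12 libraries.

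All 57133 gene names in the count files matched GENCODE 29, 216 of them with several gene identifiers, and 30296 had a count. No column of another sample was used. Coordinates are those of GENCODE 29 on GRCh38. Libraries held 13168749 to 18321114 counts. A floor of 3 counts over the 3 libraries of a group equals 0.0587 CPM in mVenus, 0.0652 in p16, 0.0651 with Torin2 and 0.0660 in p21. Floors and exact 95% intervals cover counting error only.

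Genes were filtered with filterByExpr (14504 kept), scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. All 12 libraries entered a single fit with a coefficient per group (8 residual degrees of freedom), and contrasts were two-sided with Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 3.94%. The 32 gene lists (1104 symbols, 13 matched by an older symbol and 1, TIP60, unmatched) were fixed before the data were examined. The 30 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), two-sided, adjusted over the lists. The counts of members that rose or fell come from the edgeR test over all genes.

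Named genes followed a rule set before the data were examined. It took CDKN2A, CDKN1A, MKI67, LMNB1, GLB1, BRCA1, BRCA2, TP53BP1, XRCC6, IL6 and CXCL8 always. Some genes taken by the rule are not reported here. It added the 5 largest log2 rises and falls with adjusted p under 0.05, at least 5 CPM in the higher group and no overlap of replicates (for which chance gives 10% of genes). It took up to 2 rises and 2 falls per called list, and of the homologous recombination, end joining, p53, secretory and lysosome lists in every comparison. The tested markers of the leukocyte and endothelial lists are named as well. Fold changes against a group at 0 counts are lower bounds against the floor, and genes with 1 to 3 counts are given as a ratio of counts.

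The code was tested on simulated counts with 200 changed genes. For p16 against mVenus it recovered 47.8%, 67.2% and 83.3% of genes changed 1.2-, 1.5- and 2-fold, for p21 35.8%, 80.6% and 78.8%, for Torin2 35.8%, 56.7% and 84.8% and for p21 against p16 32.8%, 61.2% and 77.3%, with 9, 13, 3 and 4 false calls among 13920, 13905, 13882 and 13879 genes. A list shifted 1.5-fold was called in each comparison and 0 of the others were.

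Alternatives were other scalings (DESeq2 size factors, upper quartile), no low-count filter, the DESeq2 1.42.0 Wald test, only the libraries compared, a replicate block, each library left out, and for lists an estimated correlation and fry. Ranges of p over alternatives leave out the block and fry. Comparisons that share libraries were set beside 20 simulations of unchanged groups. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.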

Results

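Messenger RNA was sequenced from MCF10-A cells, an established, non-tumorigenic human breast epithelial line, that carried a doxycycline-inducible transgene. The transgene encoded the yellow fluorescent protein mVenus alone, mVenus fused to p16, or mVenus fused to p21. Both p16 and p21 are inhibitors of cyclin-dependent kinases that stop the cell cycle. Cells were collected at day 5 of induction. The p16 cells were given either DMSO, the solvent, or 100 nM Torin2, an inhibitor of the kinase mTOR. The 4 groups are called mVenus, p16, p16 with Torin2 and p21, and each held 3 biological replicates according to the series description. The 12 libraries held 13168749 to 18321114 assigned counts, and 14504 genes had enough counts to be tested. Levels are given as CPM, counts scaled to library size, as mean ± SD over the 3 libraries of a group. Values in brackets after a gene name are log2 fold changes ± SE from the edgeR quasi-likelihood test, and genes described as having risen or fallen passed a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. A p beside a list comes from camera, the competitive gene set test of limma, with a preset correlation between genes of 0.01. Highest and lowest in a list refer to log2 fold changes of members that passed. The series concerns DNA damage signalling and DNA repair in senescent cells, which set the choice of gene lists.

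CDKN2A, the gene of p16 (chromosome 9, 21967753 to 21995301, GRCh38), had 0 counts in all 12 libraries, including those of the p16 cells. Over the 3 p16 libraries, 0 counts allow a level of up to 0.0652 CPM, counting error only. Reads of a transgene need not be counted under this gene, so this sets no limit on its transcript. Its neighbour CDKN2B also had 0 counts in all 12 libraries. The counts therefore give no check on which libraries carried the p16 transgene. CDKN1A, the gene of p21 (chromosome 6, 36676460 to 36687339), stood at 712 ± 13 CPM in mVenus, 570.3 ± 30.1 in p16, 259 ± 17.0 in p16 with Torin2 and 889 ± 16.5 in p21. It was 1.25-fold higher in p21 than in mVenus (log2 fold change 0.32 ± 0.04, adjusted p = 2.08e-06), 1.25-fold lower in p16 (log2 fold change -0.32 ± 0.04, adjusted p = 1.65e-06) and 1.56-fold higher in p21 than in p16 (log2 fold change 0.64 ± 0.04, adjusted p = 9.12e-11). Transgene and endogenous transcripts were not separated in the counts.

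The libraries grouped by condition. On log2 CPM, the first principal component held 38.1% of the variance and the second 32.7%, and the 4 groups lay apart from each other on their plane. Replicates of a group correlated with r of 0.992 or more across genes, and their counts differed by more than sampling noise (chi-square per degree of freedom 1.61 to 6.15). Mitochondrially encoded transcripts took 3.87 ± 0.0305% of counts in mVenus, 6.62 ± 0.290% in p16, 6.02 ± 0.597% in p16 with Torin2 and 6.49 ± 0.456% in p21. Cytosolic ribosomal protein transcripts took 2.74 ± 0.0369%, 3.54 ± 0.0666%, 6.52 ± 0.0274% and 2.72 ± 0.0777% in the same order.

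**Figure D1:**
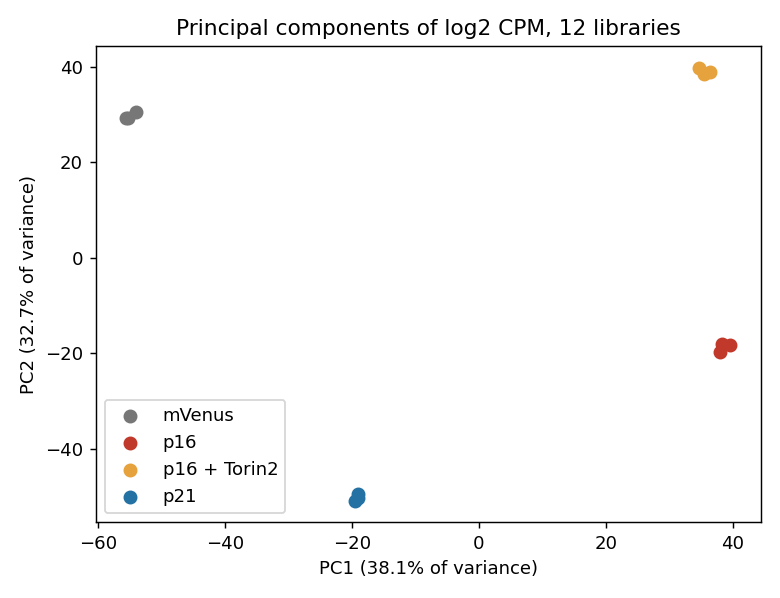
Each point is 1 of the 12 libraries, coloured by group, on the first (38.1% of variance) and second (32.7%) principal component of log2 CPM. The 3 libraries of each group lie close together and the 4 groups lie apart.

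The first comparison asks what 5 days of p16 expression did to the transcriptome relative to mVenus alone. Genes of proliferating cells fell. MKI67, a marker of cycling cells (chromosome 10, 128096659 to 128126385), was 32.8-fold lower, from 331 ± 15.6 to 10.1 ± 0.427 CPM (log2 fold change -5.03 ± 0.06, adjusted p = 1.62e-22). LMNB1, which encodes lamin B1 of the nuclear lamina (chromosome 5, 126776623 to 126837020), was 11.2-fold lower, from 54.2 ± 4.22 to 4.83 ± 0.229 CPM (log2 fold change -3.49 ± 0.11, adjusted p = 1.21e-16). The homologous recombination genes BRCA1 (chromosome 17, 43044295 to 43170245) and BRCA2 (chromosome 13, 32315474 to 32400266) fell. BRCA1 went from 47.6 ± 1.04 to 11.2 ± 0.248 CPM and BRCA2 from 26.1 ± 0.989 to 5.93 ± 1.16 CPM. In the other direction, the basal keratin KRT14 rose from 25.6 ± 2.41 to 466 ± 16.3 CPM and the interferon-stimulated gene IFIT1 from 46.1 ± 13.1 to 891 ± 137 CPM.

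The edgeR test called 4487 genes higher and 4751 lower in p16 than in mVenus, of which 1031 and 1356 changed by 2-fold or more. Among genes of at least 5 CPM in the higher group whose replicates did not overlap, the largest rises were ONECUT3, a transcription factor (7.56 ± 0.25), KRT13, a keratin of stratified epithelia (6.35 ± 0.19), the amino acid transporter SLC6A14 (6.26 ± 0.18), the serpin SERPINB13 (6.21 ± 0.33) and the TNF family ligand TNFSF18 (6.15 ± 0.38). Leaving out an mVenus library moved some of these. ONECUT3 was 8.71 without mVenus replicate 3, SERPINB13 was 5.56 and 6.93 without mVenus replicates 1 and 2, and TNFSF18 was 9.85 and 5.55 without replicates 1 and 3. MYH14, a non-muscle myosin heavy chain, and TLR2, a receptor of innate immunity, had 0 counts in the 3 p16 libraries against 6.70 ± 0.407 and 5.15 ± 0.552 CPM in mVenus. Against a floor of 3 counts over the group they were at least 103-fold and at least 78.9-fold lower. KANK4 had 1 count in the p16 libraries, a ratio of mVenus to p16 of 638 (95% exact interval 114 to 25251) from the counts, and its fitted log2 fold change of -8.88 became -10.77 without p16 replicate 1. The adhesion molecule MCAM (-5.70 ± 0.08) and PRKAA2, a catalytic subunit of AMP-activated kinase (-5.49 ± 0.23), completed the largest falls.

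The cell cycle, homologous recombination, mismatch repair and damage signalling lists fell in p16. Some share genes (EXO1, CLSPN), so list results are not independent. In DNA replication, 48 of 50 tested members fell and 0 rose (median log2 fold change -2.02, adjusted p = 6.05e-19; 0 up and 49 down adjusted over the list alone). The thymidine kinase TK1 (-5.30 ± 0.13) and the checkpoint adaptor CLSPN (-4.99 ± 0.12) were lowest. In G2 and mitosis, 52 of 54 tested members fell and 1 rose (median log2 fold change -3.18, adjusted p = 4.50e-21; 2 up and 52 down adjusted over the list alone). The phosphatase CDC25B (0.26 ± 0.05) rose. In homologous recombination and Fanconi anaemia, 33 of 43 tested members fell and 2 rose (median log2 fold change -0.95, adjusted p = 2.59e-08). The nuclease EXO1 (-4.06 ± 0.10) and the helicase BLM (-3.43 ± 0.16) were lowest, while FANCF (0.32 ± 0.09) and MRE11 (0.13 ± 0.06) rose. In non-homologous end joining, 11 of 19 tested members fell and 0 rose (median log2 fold change -0.16, adjusted p = 0.0183, but adjusted p = 0.0507 with an estimated correlation (0.00983 to 0.0507 over 11 alternatives)). Its largest falls were POLQ, a polymerase of the alternative end-joining route (-2.70 ± 0.14), and MAD2L2 (-0.96 ± 0.09), and XRCC6, the Ku70 subunit, was 1.08-fold lower (log2 fold change -0.11 ± 0.03, adjusted p = 0.00564). TP53BP1 was 1.37-fold lower, from 76.6 ± 3.50 to 55.9 ± 2.39 CPM (log2 fold change -0.46 ± 0.05, adjusted p = 7.48e-08), with 28.7% of its exonic bases shared with TUBGCP4, so its level is uncertain. In mismatch repair, 16 of 20 tested members fell and 2 rose (median log2 fold change -0.77, adjusted p = 1.70e-05; 2 up and 17 down adjusted over the list alone). MLH3 (0.29 ± 0.05) and PMS2 (0.22 ± 0.08) rose. In base excision repair, 15 of 23 tested members fell and 3 rose (median log2 fold change -0.34, adjusted p = 0.0114, but adjusted p = 0.0712 with an estimated correlation (0.00140 to 0.0712 over 11 alternatives)). The glycosylase NEIL3 (-4.10 ± 0.22) was lowest and the endonuclease APEX1 (0.39 ± 0.04) was highest. In DNA damage signalling, 19 of 31 tested members fell and 4 rose (median log2 fold change -0.31, adjusted p = 0.00416). The ubiquitin ligase MDM2 (0.46 ± 0.06) rose. The call of MRE11 ended when any of the 6 libraries was left out (adjusted p 0.0513 to 0.154 by edgeR), in the DESeq2 Wald test (0.0914), with only these 6 libraries (0.0624) and with upper quartile scaling (0.0562), 0.0239 to 0.154 over 11 alternatives. That of PMS2 ended without mVenus replicates 1 or 2 or p16 replicates 2 or 3 (0.0539 to 0.103, 0.00741 to 0.103 over 11 alternatives), and that of XRCC6 without the low-count filter (adjusted p = 0.301, 0.00319 to 0.301 over 11 alternatives).

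Nuclear and cell cycle regulators also changed. In nuclear architecture in senescence, 20 of 25 tested members fell and 2 rose (median log2 fold change -1.08, adjusted p = 5.26e-08). The condensin subunit NCAPH (-4.23 ± 0.13) fell and the chromatin protein HMGA2 (0.55 ± 0.10) rose. NCAPG (-4.29) and HIRA (0.46) of this list share 33.1% and 66.5% of their exonic bases with another gene and are uncertain. Among E2F and cyclin-dependent kinase regulators, 16 of 26 tested members fell and 4 rose (median log2 fold change -0.46, adjusted p = 0.0107; 5 up and 16 down adjusted over the list alone). The inhibitor gene CDKN2C (-3.67 ± 0.13) and the repressor E2F7 (-3.53 ± 0.12) were lowest and the D-type cyclins CCND2 (1.44 ± 0.06) and CCND1 (0.40 ± 0.03) were highest.

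The basal and luminal lists rose and the mesenchymal list fell in p16. Among interferon-stimulated genes, 38 of 43 tested members rose and 3 fell (median log2 fold change 2.02, adjusted p = 2.40e-14, but adjusted p = 0.105 with an estimated correlation (1.44e-24 to 0.105 over 11 alternatives); 38 up and 4 down adjusted over the list alone). IFIT1 was 19.3-fold higher, from 46.1 ± 13.1 to 891 ± 137 CPM (log2 fold change 4.27 ± 0.14, adjusted p = 2.62e-16), and MX1 (-1.97 ± 0.21) and GBP2 (-0.37 ± 0.06) fell. XAF1 had 72 counts in p16 against 2 in mVenus, a ratio of 40.0 (95% exact interval 10.7 to 337), its fitted value of 5.07 became 7.60 without mVenus replicate 1, and 38.3% of its exonic bases are shared. Of leukocyte markers, CSF1R (1.03 ± 0.05) and CD14 (1.30 ± 0.09) rose and ITGAX (-2.09 ± 0.46) fell, while PTPRC, CD3E and TYROBP had 0 counts in p16. Of endothelial markers, ROBO4 (3.19 ± 0.16) and PECAM1 (1.14 ± 0.29) rose and KDR did not pass (0.39 ± 0.21). Each of these marker lists had 3 tested members, too few for a list test. In keratinising differentiation, 21 of 22 tested members rose and 0 fell (median log2 fold change 2.05, adjusted p = 9.75e-09, but adjusted p = 0.0507 with an estimated correlation (2.14e-12 to 0.0507 over 11 alternatives)). The largest changes were in KRT13 and KRT16, the latter from 46.0 ± 6.27 to 912 ± 30.4 CPM. In basal mammary epithelium, 13 of 22 tested members rose and 6 fell (median log2 fold change 0.76, adjusted p = 0.00425). KRT14 (chromosome 17, 41582279 to 41586921) was 18.3-fold higher, from 25.6 ± 2.41 to 466 ± 16.3 CPM (log2 fold change 4.19 ± 0.07, adjusted p = 1.53e-20), KRT15 followed (4.0 ± 0.07), and the laminin gene LAMB3 (-1.49 ± 0.04) fell. In luminal mammary epithelium, 12 of 14 tested members rose and 1 fell (median log2 fold change 0.90, adjusted p = 8.39e-06). KRT19 (3.85 ± 0.53), at low counts, and the claudin CLDN4 (2.30 ± 0.08) rose and KRT7 (-0.34 ± 0.04) fell. In the mesenchymal and fibroblast list, 17 of 20 tested members fell and 0 rose (median log2 fold change -1.68, adjusted p = 1.08e-07), and fibronectin, FN1 (chromosome 2, 215360440 to 215436172), was 39.5-fold lower, from 2440.4 ± 152 to 61.7 ± 5.04 CPM (log2 fold change -5.31 ± 0.10, adjusted p = 1.14e-19).

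The ribosomal, ribosome biogenesis and nuclear-encoded oxidative phosphorylation lists rose. Among cytosolic ribosomal proteins, 70 of 74 tested members rose and 0 fell (median log2 fold change 0.46, adjusted p = 1.42e-18). RPL13A (0.81 ± 0.04) and RPL36 (0.78 ± 0.03) were highest. In ribosome biogenesis, 33 of 49 tested members rose and 4 fell (median log2 fold change 0.33, adjusted p = 8.37e-06; 34 up and 4 down adjusted over the list alone). RRS1 (0.79 ± 0.06) rose and the nucleolar factor TCOF1 (-0.53 ± 0.04) fell. PPAN, the highest of this list (0.95), is overlapped over 59.8% of its exonic bases. In nuclear-encoded oxidative phosphorylation, 38 of 50 tested members rose and 1 fell (median log2 fold change 0.26, adjusted p = 5.06e-07). ATP5MC2 (0.62 ± 0.04) was highest and NDUFB6 (-0.24 ± 0.07) fell. Of the mitochondrially encoded mRNAs, 13 of 13 tested members rose and 0 fell (median log2 fold change 0.68, adjusted p = 1.45e-05, but adjusted p = 0.281 with an estimated correlation (2.78e-09 to 0.281 over 11 alternatives)), MT-CO1 from 4698 ± 201 to 9691 ± 313 CPM. Among FOXO targets, 19 of 31 tested members rose and 8 fell (median log2 fold change 0.31, adjusted p = 0.0118, but adjusted p = 0.0885 with an estimated correlation (0.000238 to 0.0885 over 11 alternatives)). CITED2 (1.81 ± 0.08) and TXNIP (1.39 ± 0.03) were highest. In fatty acid synthesis, 10 of 16 tested members rose and 4 fell (median log2 fold change 0.40, adjusted p = 0.0489, but adjusted p = 0.0885 with an estimated correlation (0.00556 to 0.0885 over 11 alternatives)). The acetate-activating enzyme ACSS2 (1.54 ± 0.05) and FASN, the fatty acid synthase, rose, the latter from 722 ± 31.9 to 1724 ± 98.2 CPM, and the desaturase FADS1 fell from 50.9 ± 0.495 to 5.27 ± 0.437 CPM. The fatty acid call was lost without mVenus replicate 3 (adjusted p = 0.0505), without p16 replicate 2 (0.0531), with DESeq2 size factors (0.0517) and without overlapped genes (0.0528, 0.00556 to 0.0885 over 11 alternatives).

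Other lists did not pass the list test in p16, although many of their members changed. They were p53 targets (16 up and 14 down of 35, median 0.05, adjusted p = 0.631), secretory factors of senescence (17 up and 19 down of 41, median 0.03, adjusted p = 0.631), lysosome (27 up and 17 down of 53, median 0.13, adjusted p = 0.188, 28 and 17 adjusted over the list alone), NF-kappaB targets (12 up and 8 down of 26, median 0.14, adjusted p = 0.631) and autophagy (12 up and 13 down of 44, median -0.01, adjusted p = 0.969). Likewise nucleotide excision repair (9 up and 7 down of 22, median 0.02, adjusted p = 0.677, 10 and 7 adjusted over the list alone), cholesterol synthesis (6 up and 11 down of 24, median -0.07, adjusted p = 0.270, 6 and 12 adjusted over the list alone), ATF4 targets (12 up and 15 down of 36, median 0.00, adjusted p = 0.618), glycolysis and hypoxia (13 up and 11 down of 29, median 0.10, adjusted p = 0.454) and immediate early and heat shock (12 up and 9 down of 25, median 0.08, adjusted p = 0.240) were not called. Among secretory genes, SERPINB2 (3.68 ± 0.08) and interleukin 8, CXCL8 (chromosome 4, 73740506 to 73743716), rose, the latter from 7.91 ± 1.11 to 67.4 ± 3.79 CPM. IL6 held at most 2 counts in any library and was not tested. Of p53 targets, TRIM22 (1.95 ± 0.08) and PERP (1.85 ± 0.04) rose and DRAM1 (-1.15 ± 0.09) fell. Of lysosomal genes, LIPA (1.22 ± 0.05) rose, ARSB (-1.49 ± 0.07) fell, CTSD (1.45) is overlapped over 52.7% of its exonic bases, and GLB1, the lysosomal beta-galactosidase, was 1.28-fold higher, from 77.7 ± 0.617 to 99.4 ± 5.99 CPM (log2 fold change 0.35 ± 0.05, adjusted p = 1.06e-06). Without the low-count filter the lysosome list passed (adjusted p = 0.0216, 0.0216 to 0.478 over 11 alternatives). For the secretory, nucleotide excision repair, autophagy and glycolysis lists the median, mean and test differed in sign.

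Of the 30 lists, 20 passed camera with a preset correlation of 0.01, against 13 with an estimated correlation. The p16 and mVenus cells are separate lines and no uninduced libraries were analysed, so induction and line cannot be separated.

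**Figure D2:**
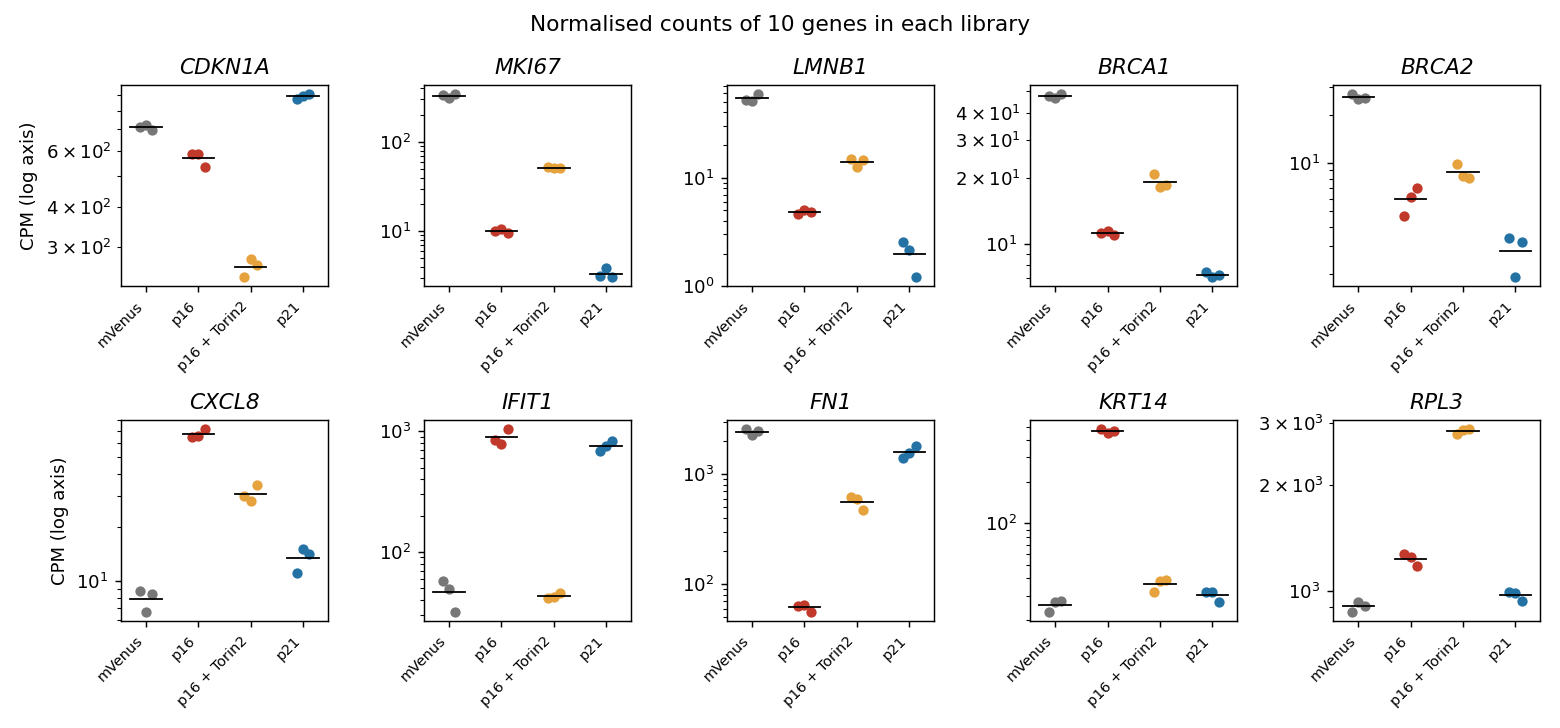
Points are CPM (counts scaled to library size, log axis) of a gene in each of the 12 libraries, grouped by condition, and black lines are group means of 3 libraries. MKI67, LMNB1, BRCA1 and BRCA2 were lowest in p21 and next lowest in p16, IFIT1 was high in p16 and p21, KRT14 was high in p16, and RPL3 was high in p16 with Torin2.

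The second comparison asks the same of p21. Proliferation genes fell. MKI67 was 98.3-fold lower, from 331 ± 15.6 to 3.35 ± 0.425 CPM (log2 fold change -6.62 ± 0.07, adjusted p = 2.62e-23), and LMNB1 was 27.6-fold lower, from 54.2 ± 4.22 to 1.98 ± 0.697 CPM (log2 fold change -4.79 ± 0.13, adjusted p = 1.89e-17). BRCA1 fell from 47.6 ± 1.04 to 7.25 ± 0.218 CPM and BRCA2 from 26.1 ± 0.989 to 2.83 ± 0.792 CPM. The interferon-stimulated gene IFIT1 was 16.4-fold higher, from 46.1 ± 13.1 to 753 ± 66.1 CPM (log2 fold change 4.03 ± 0.14, adjusted p = 8.21e-16). Genes of cholesterol synthesis fell, among them INSIG1, a regulator of the pathway, from 68.1 ± 2.97 to 10.1 ± 0.633 CPM.

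The edgeR test called 4085 genes higher and 4102 lower in p21 than in mVenus, with 826 and 941 changed by 2-fold or more. Besides IFIT1, the largest rises within the same limits were in the myosin-binding protein gene MYBPC1, the zinc finger gene ZNF813 (5.75 ± 0.35), the transporter ABCA8 (4.85 ± 0.11) and the GTPase RAB25 (4.12 ± 0.24). MYBPC1 had 246 counts against 3 in mVenus, a ratio of 92.2 (95% exact interval 31.2 to 450.2). ZNF813 was 7.37 and 5.15 without mVenus replicates 2 and 3. MYH14 and TLR2 again had 0 counts, at least 102-fold and at least 78.0-fold lower than in mVenus. TROAP had 1 count against 677 in mVenus, a ratio of mVenus to p21 of 602 (95% exact interval 108 to 23816), and its fitted value of -8.79 became -10.70 without p21 replicate 3. DLGAP5, a mitotic spindle protein, stood at -7.12 ± 0.20 and at -8.44 without p21 replicate 3, and the transcription factor MYBL2 (-7.02 ± 0.13) fell with it.

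All tested members of the main proliferation lists fell in p21. In G2 and mitosis, 54 of 54 tested members fell and 0 rose (median log2 fold change -4.19, adjusted p = 2.94e-33), and in DNA replication, 50 of 50 tested members fell and 0 rose (median log2 fold change -2.23, adjusted p = 1.75e-27). MCM10 (-6.64 ± 0.18) and TK1 (-6.28 ± 0.15) were lowest. In homologous recombination and Fanconi anaemia, 34 of 43 tested members fell and 0 rose (median log2 fold change -1.24, adjusted p = 4.83e-12). BLM (-4.87 ± 0.20) was lowest. In non-homologous end joining, 10 of 19 tested members fell and 0 rose (median log2 fold change -0.29, adjusted p = 0.00374). POLQ (-3.76 ± 0.16) and POLM (-0.81 ± 0.09) were lowest and XRCC6 was 1.22-fold lower (log2 fold change -0.29 ± 0.03, adjusted p = 1.86e-07). TP53BP1 did not pass (log2 fold change 0.09 ± 0.05, adjusted p = 0.124) except without the low-count filter (adjusted p = 0.0427, 0.0427 to 0.377 over 11 alternatives). In mismatch repair, 17 of 20 tested members fell and 2 rose (median log2 fold change -0.79, adjusted p = 6.11e-07). MLH3 (0.50 ± 0.05) and PMS2 (0.27 ± 0.08) rose and EXO1 (-4.29 ± 0.11) was lowest. In base excision repair, 11 of 23 tested members fell and 2 rose (median log2 fold change -0.21, adjusted p = 0.00696, but adjusted p = 0.0590 with an estimated correlation (0.000954 to 0.0590 over 11 alternatives)). POLB (0.39 ± 0.07) rose and NEIL3 (-5.55 ± 0.27) was lowest. In DNA damage signalling, 19 of 31 tested members fell and 5 rose (median log2 fold change -0.29, adjusted p = 0.00288). CLSPN (-5.42 ± 0.13) was lowest and ABRAXAS1 (0.61 ± 0.13) rose. In nuclear architecture, 23 of 25 tested members fell and 1 rose (median log2 fold change -1.38, adjusted p = 4.14e-12). The histone chaperone ASF1B (-5.75 ± 0.17) was lowest and HIRA (0.52 ± 0.10), overlapped over 66.5% of its exonic bases, rose. Among E2F and cyclin-dependent kinase regulators, 16 of 26 tested members fell and 4 rose (median log2 fold change -0.34, adjusted p = 0.00615; 5 up and 16 down adjusted over the list alone). E2F8 (-5.47 ± 0.27) was lowest and CCND2 (1.2 ± 0.06) and CCND1 (1.15 ± 0.03) rose.

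The p53, ATF4 and FOXO lists rose and the cholesterol list fell in p21. Among p53 targets, 28 of 35 tested members rose and 3 fell (median log2 fold change 0.35, adjusted p = 2.65e-06; 29 up and 3 down adjusted over the list alone). TRIM22 (1.97 ± 0.08) and the cytokine GDF15 (1.85 ± 0.10) were highest and DDB2 (-0.59 ± 0.06) was lowest. Among interferon-stimulated genes, 37 of 43 tested members rose and 3 fell (median log2 fold change 1.93, adjusted p = 3.55e-16, but adjusted p = 0.0936 with an estimated correlation (2.00e-27 to 0.0936 over 11 alternatives)). CXCL11 (-1.84 ± 0.24) and MX1 (-1.37 ± 0.20) fell. IFITM1 (3.76) shares 32.5% of its exonic bases with another gene. Of leukocyte markers CSF1R (1.12 ± 0.05) and CD14 (0.58 ± 0.10) rose and ITGAX (-3.34 ± 0.56) fell, and PTPRC, CD3E and TYROBP had 0 counts. The endothelial markers ROBO4 (-1.16 ± 0.27), PECAM1 (-1.05 ± 0.39) and KDR (-0.78 ± 0.24) fell. Among ATF4 targets, 21 of 36 tested members rose and 5 fell (median log2 fold change 0.28, adjusted p = 4.47e-05; 23 up and 5 down adjusted over the list alone). The hormone gene STC2 (3.07 ± 0.07) and CHAC1 (2.27 ± 0.14) were highest. In cholesterol synthesis, 23 of 24 tested members fell and 0 rose (median log2 fold change -0.89, adjusted p = 4.69e-12), and ACAT2 (-2.37) is overlapped over 52.3% of its exonic bases. In the lysosome list, 30 of 53 tested members rose and 8 fell (median log2 fold change 0.19, adjusted p = 0.000455, but adjusted p = 0.0839 with an estimated correlation (4.88e-07 to 0.0839 over 11 alternatives)). FUCA1 (1.63 ± 0.05) and GAA (1.28 ± 0.06) were highest and GLB1 was 1.24-fold higher (log2 fold change 0.31 ± 0.05, adjusted p = 9.13e-06). Among FOXO targets, 20 of 31 tested members rose and 5 fell (median log2 fold change 0.51, adjusted p = 9.17e-05; 20 up and 6 down adjusted over the list alone). CITED2 (1.90 ± 0.08) and the mitochondrial superoxide dismutase SOD2 (1.74 ± 0.06) were highest. Of the mitochondrially encoded mRNAs, 13 of 13 tested members rose and 0 fell (median log2 fold change 0.84, adjusted p = 1.11e-06, but adjusted p = 0.225 with an estimated correlation (2.34e-11 to 0.225 over 11 alternatives)), MT-ND1 from 1797 ± 89.6 to 3904 ± 385 CPM. In ribosome biogenesis, 25 of 49 tested members rose and 5 fell (median log2 fold change 0.15, adjusted p = 0.0104; 25 up and 6 down adjusted over the list alone). TCOF1 (-1.39 ± 0.05) was lowest. In autophagy, 16 of 44 tested members rose and 7 fell (median log2 fold change 0.07, adjusted p = 0.0421, but adjusted p = 0.0590 with an estimated correlation (0.00243 to 0.0645 over 11 alternatives); 15 up and 7 down adjusted over the list alone). WIPI1 (0.80 ± 0.09) rose and FNIP2 (-1.05 ± 0.12) fell. SQSTM1 (log2 fold change 1.18 ± 0.49, adjusted p = 0.0474) rested on 10 to 17 counts per p21 library and was not called by DESeq2 or when any of mVenus replicates 1 or 3 or p21 replicates 1, 2 or 3 was left out (adjusted p 0.0599 to 0.166, 0.00824 to 0.166 over 11 alternatives). The autophagy call ended without mVenus replicate 3 (adjusted p = 0.0547) and without overlapped genes (0.0645).

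The remaining lists did not pass in p21. They were secretory factors of senescence (19 up and 13 down of 41, median 0.19, adjusted p = 0.482), NF-kappaB targets (12 up and 7 down of 26, median 0.16, adjusted p = 0.432), fatty acid synthesis (5 up and 9 down of 16, median -0.17, adjusted p = 0.106, 6 and 9 adjusted over the list alone), cytosolic ribosomal proteins (28 up and 11 down of 74, median 0.04, adjusted p = 0.272), nuclear-encoded oxidative phosphorylation (15 up and 11 down of 50, median 0.02, adjusted p = 0.635, 14 and 11 adjusted over the list alone) and nucleotide excision repair (10 up and 6 down of 22, median 0.10, adjusted p = 0.556). The same held for glycolysis and hypoxia (9 up and 10 down of 29, median -0.04, adjusted p = 0.644), immediate early and heat shock (6 up and 13 down of 25, median -0.20, adjusted p = 0.111, 7 and 15 adjusted over the list alone), basal mammary epithelium (10 up and 5 down of 22, median 0.15, adjusted p = 0.171), luminal mammary epithelium (7 up and 3 down of 14, median 0.22, adjusted p = 0.0682), keratinising differentiation (10 up and 9 down of 22, median 0.52, adjusted p = 0.577) and mesenchymal and fibroblast (7 up and 10 down of 20, median -0.27, adjusted p = 0.577). Without the low-count filter the ribosomal protein, luminal and basal lists passed (adjusted p = 0.0178, 0.0334 and 0.0411, against up to 0.757, 0.247 and 0.252 in other alternatives). Among secretory genes, IGFBP4 (2.84 ± 0.24) and TGFB2 (2.28 ± 0.12) rose, CXCL8 was 1.69-fold higher, from 7.91 ± 1.11 to 13.4 ± 2.14 CPM (log2 fold change 0.75 ± 0.13, adjusted p = 3.53e-05), and MMP9 and INHBA had 0 counts in p21, at least 11.8-fold and at least 2.90-fold lower than in mVenus. With both at their bounds the median of the secretory list stayed at 0.19. For the secretory, keratinising and nucleotide excision repair lists the median and mean differed in sign.

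Of the 30 lists, 18 passed camera with the preset correlation and 13 with an estimated one. The p21 and mVenus cells are separate lines as well, so induction and line cannot be separated in this comparison.

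The third comparison asks what Torin2 did within the p16 line. Whether mTOR mediated its effects was not tested. Transcripts of ribosomal proteins and of proliferation were higher with Torin2, and those of sterol synthesis genes were lower. RPL3, a protein of the large ribosomal subunit (chromosome 22, 39312882 to 39320389), was 2.30-fold higher, from 1235 ± 49.8 to 2847 ± 48.1 CPM (log2 fold change 1.2 ± 0.04, adjusted p = 2.33e-16). MKI67 was 5.10-fold higher, from 10.1 ± 0.427 to 51.6 ± 0.647 CPM (log2 fold change 2.35 ± 0.07, adjusted p = 1.05e-16), against 331 ± 15.6 CPM in mVenus. LMNB1 rose from 4.83 ± 0.229 to 14.0 ± 1.33 CPM and BRCA1 from 11.2 ± 0.248 to 19.3 ± 1.49 CPM. DHCR7, the last enzyme of a cholesterol synthesis route, was 5.18-fold lower, from 96.4 ± 5.68 to 18.6 ± 0.607 CPM (log2 fold change -2.37 ± 0.06, adjusted p = 2.05e-17), and CDKN1A was 2.20-fold lower, from 570.3 ± 30.1 to 259 ± 17.0 CPM (log2 fold change -1.14 ± 0.04, adjusted p = 1.39e-14).

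The edgeR test called 4400 genes higher and 4208 lower with Torin2, with 682 and 934 changed by 2-fold or more. The largest rises within these limits were the scaffold protein AKAP12 (4.40 ± 0.12), FN1 (3.19 ± 0.10), TGFB1I1 (3.15 ± 0.13), the protease inhibitor TFPI2 (3.15 ± 0.26) and the pseudogene RPSAP52 (3.09 ± 0.30), which can share reads with its parent gene. The largest falls were the nucleotide receptor P2RY6, ATP13A4 (-6.45 ± 0.35), the calcium-binding protein S100A8 (-5.56 ± 0.11), the peptide transporter SLC15A2 (-5.49 ± 0.18) and BBOX1 (-5.31 ± 0.19). P2RY6 had 2 counts with Torin2 against 399, a ratio of p16 to p16 with Torin2 of 199.9 (95% exact interval 55.0 to 1656). ATP13A4 was -7.12 without replicate 1 of the Torin2 group.

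The proliferation, homologous recombination and nuclear architecture lists rose with Torin2. In G2 and mitosis, 45 of 54 tested members rose and 4 fell (median log2 fold change 1.12, adjusted p = 1.64e-09; 45 up and 5 down adjusted over the list alone). UBE2C (2.36 ± 0.16) was highest and CKS1B (-0.54 ± 0.08) and PLK1 (-0.51 ± 0.08) fell. In DNA replication, 36 of 50 tested members rose and 2 fell (median log2 fold change 0.74, adjusted p = 4.28e-07). The licensing factor CDT1 (2.92 ± 0.14) and TK1 (2.19 ± 0.20) were highest. The call of POLA2 (-0.48 ± 0.18) ended without p16 replicate 3, Torin2 replicates 1 or 2 or the low-count filter and by DESeq2 (adjusted p 0.0721 to 0.103, 0.0175 to 0.103 over 11 alternatives), and that of ORC6 (-0.32 ± 0.12) without p16 replicates 2 or 3 or Torin2 replicates 1 or 2 and by DESeq2 (0.0569 to 0.102, 0.00864 to 0.102 over 11 alternatives). In homologous recombination and Fanconi anaemia, 30 of 43 tested members rose and 1 fell (median log2 fold change 0.56, adjusted p = 4.10e-06). EME1 (1.89 ± 0.40) and BLM (1.64 ± 0.20) were highest and BRCA2 rose from 5.93 ± 1.16 to 8.77 ± 0.991 CPM. The scaffold SLX4 (-0.32 ± 0.10) fell, but not without Torin2 replicate 1 (adjusted p = 0.0746, 0.00167 to 0.0746 over 11 alternatives). In mismatch repair, 13 of 20 tested members rose and 0 fell (median log2 fold change 0.26, adjusted p = 0.00338, but adjusted p = 0.101 with an estimated correlation (0.000122 to 0.101 over 11 alternatives); 13 up and 1 down adjusted over the list alone). EXO1 (1.61 ± 0.14) was highest. In nuclear architecture, 18 of 25 tested members rose and 3 fell (median log2 fold change 0.41, adjusted p = 0.000117; 20 up and 3 down adjusted over the list alone). HMGA2 (2.38 ± 0.08) was highest and the lamin LMNA (-0.33 ± 0.04) fell. The non-homologous end joining list did not pass (8 up and 4 down of 19, median 0.18, adjusted p = 0.263), and of its members POLQ (0.99 ± 0.17) and RIF1 (0.80 ± 0.06) rose, LIG4 (-0.76 ± 0.10) fell, and TP53BP1 and XRCC6 changed by 0.27 ± 0.05 and -0.12 ± 0.03.

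Translation lists rose. Among cytosolic ribosomal proteins, 72 of 74 tested members rose and 0 fell (median log2 fold change 0.78, adjusted p = 8.53e-29). RPL10 (1.26), the highest, is overlapped over 55.5% of its exonic bases. In ribosome biogenesis, 31 of 49 tested members rose and 2 fell (median log2 fold change 0.17, adjusted p = 0.000129). POLR1E (0.91 ± 0.07) rose and PNO1 (-0.34 ± 0.06) and NOP10 (-0.32 ± 0.04) fell. FBL, fibrillarin, was fitted at 3.24 ± 0.75, but had 16 counts in the lowest and 159 in the highest Torin2 library, and stood at 1.25 without Torin2 replicate 3, and DESeq2 gave it no adjusted p.

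The p53, lipid synthesis and lysosome lists fell. Among interferon-stimulated genes, 42 of 43 tested members fell and 0 rose (median log2 fold change -2.71, adjusted p = 1.02e-21, but adjusted p = 0.0672 with an estimated correlation (1.43e-38 to 0.0672 over 11 alternatives)). CXCL10 was 38.8-fold lower, from 3.68 ± 1.03 to 0.0867 ± 0.0996 CPM (log2 fold change -5.28 ± 0.48, adjusted p = 8.85e-09) and stood at -6.51 without Torin2 replicate 1, and IFITM1 (-5.00) is overlapped over 32.5% of its exonic bases. The leukocyte markers CSF1R (-1.10 ± 0.06) and CD14 (-1.27 ± 0.10) and the endothelial markers ROBO4 (-1.83 ± 0.13) and PECAM1 (-3.18 ± 0.40) fell too, and ITGAX (0.18 ± 0.61) and KDR (-0.33 ± 0.21) did not pass. Among p53 targets, 28 of 35 tested members fell and 3 rose (median log2 fold change -0.53, adjusted p = 2.86e-07; 4 up and 28 down adjusted over the list alone). TRIM22 (-3.15 ± 0.09) was lowest and BTG1 (0.43 ± 0.06) and DRAM1 (0.40 ± 0.10) rose. In cholesterol synthesis, 22 of 24 tested members fell and 1 rose (median log2 fold change -1.58, adjusted p = 2.54e-13). MVD (-2.35 ± 0.07) fell beside DHCR7. The member that rose, PMVK (0.18 ± 0.07), lost its call without p16 replicates 1 or 2, Torin2 replicate 3 or the low-count filter, by DESeq2 and with only these 6 libraries (adjusted p 0.0575 to 0.174, 0.00782 to 0.174 over 11 alternatives). In fatty acid synthesis, 12 of 16 tested members fell and 1 rose (median log2 fold change -0.92, adjusted p = 5.86e-06; 1 up and 13 down adjusted over the list alone). The desaturases FADS2 (-3.95 ± 0.11) and SCD (-2.76 ± 0.04) were lowest and GPAM (0.32 ± 0.06) rose. In the lysosome list, 33 of 53 tested members fell and 9 rose (median log2 fold change -0.41, adjusted p = 8.87e-06). The protease CTSS (-3.44 ± 0.20) was lowest, CTSH (0.72 ± 0.06) was highest and GLB1 was 1.73-fold lower (log2 fold change -0.79 ± 0.05, adjusted p = 1.41e-11). Among NF-kappaB targets, 12 of 26 tested members fell and 3 rose (median log2 fold change -0.26, adjusted p = 0.0169, but adjusted p = 0.0921 with an estimated correlation (0.000645 to 0.0921 over 11 alternatives)). The chemokines CXCL2 (-1.70 ± 0.27) and CXCL1 (-1.42 ± 0.13) fell and IL1B (0.90 ± 0.13) rose. CXCL8 was 2.18-fold lower, from 67.4 ± 3.79 to 30.9 ± 3.25 CPM (log2 fold change -1.12 ± 0.08, adjusted p = 2.33e-10).

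The luminal list fell and the mesenchymal list rose. In keratinising differentiation, 19 of 22 tested members fell and 2 rose (median log2 fold change -1.16, adjusted p = 1.10e-06, but adjusted p = 0.0921 with an estimated correlation (3.93e-10 to 0.0921 over 11 alternatives)). S100A9 (-4.44 ± 0.08) fell beside S100A8, while TGM1 (1.71 ± 0.38) and SBSN (1.70 ± 0.10) rose. In luminal mammary epithelium, 11 of 14 tested members fell and 1 rose (median log2 fold change -0.88, adjusted p = 0.000142). AGR2 (-3.15 ± 0.49) was lowest and ALDH1A3 (0.92 ± 0.04) rose. KRT19 (-2.29) was -3.47 without Torin2 replicate 1. In the mesenchymal and fibroblast list, 12 of 20 tested members rose and 3 fell (median log2 fold change 0.61, adjusted p = 0.0124). FN1 rose from 61.7 ± 5.04 to 564 ± 77.1 CPM, SNAI2, a transcription factor of mesenchymal cells, rose from 6.35 ± 1.01 to 31.6 ± 3.67 CPM, and COL6A1 fell from 21.4 ± 1.94 to 11.1 ± 1.54 CPM.

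Lists that did not pass with Torin2 were DNA damage signalling (15 up and 3 down of 31, median 0.16, adjusted p = 0.0743), base excision repair (10 up and 5 down of 23, median 0.14, adjusted p = 0.310, 11 and 5 adjusted over the list alone), nucleotide excision repair (6 up and 5 down of 22, median 0.00, adjusted p = 0.998), secretory factors of senescence (14 up and 19 down of 41, median -0.13, adjusted p = 0.499, 14 and 20 adjusted over the list alone), autophagy (12 up and 20 down of 44, median -0.12, adjusted p = 0.218), ATF4 targets (14 up and 13 down of 36, median -0.06, adjusted p = 0.715, 14 and 14 adjusted over the list alone) and glycolysis and hypoxia (7 up and 17 down of 29, median -0.20, adjusted p = 0.0835, 8 and 17 adjusted over the list alone). Neither did FOXO targets (11 up and 15 down of 31, median -0.13, adjusted p = 0.438), nuclear-encoded oxidative phosphorylation (7 up and 22 down of 50, median -0.10, adjusted p = 0.113), mitochondrially encoded mRNAs (2 up and 6 down of 13, median -0.09, adjusted p = 0.447), immediate early and heat shock (10 up and 9 down of 25, median 0.03, adjusted p = 0.715, 10 and 10 adjusted over the list alone), basal mammary epithelium (8 up and 8 down of 22, median -0.06, adjusted p = 0.715, 9 and 9 adjusted over the list alone) and E2F and cyclin-dependent kinase regulators (14 up and 5 down of 26, median 0.34, adjusted p = 0.105, 15 and 5 adjusted over the list alone). The damage signalling list passed without Torin2 replicate 2 (adjusted p = 0.0378, 0.0284 to 0.245 over 11 alternatives) and the glycolysis list without p16 replicate 3 (0.0483, 0.00817 to 0.295 over 11 alternatives). Of secretory genes, INHBA was 20.6-fold higher, from 0.133 ± 0.119 to 2.84 ± 0.246 CPM (log2 fold change 4.36 ± 0.38, adjusted p = 1.49e-08) at low counts, 5.31 without p16 replicate 3, and STC1 fell from 1.78 ± 0.256 to 0.369 ± 0.150 CPM. For the secretory and oxidative phosphorylation lists the median and mean differed in sign.

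Of the 30 lists, 16 passed camera with the preset correlation, 12 with an estimated one, and 28 passed fry, which asks only whether the genes of a list move on balance in a direction. Without the low-count filter, camera also called the damage signalling, glycolysis, oxidative phosphorylation and E2F lists (adjusted p = 0.0284, 0.00817, 0.0293 and 0.0305, against up to 0.245, 0.295, 0.409 and 0.170 in other alternatives).

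The fourth comparison tests p21 against p16 directly. The p21 cells held less KRT14 (25.6 CPM in mVenus), TP63 and sterol synthesis transcripts and more mesenchymal ones. KRT14 was 15.3-fold lower, from 466 ± 16.3 to 30.4 ± 2.79 CPM (log2 fold change -3.94 ± 0.07, adjusted p = 5.81e-20), and TP63, a transcription factor of basal epithelium, was 8.33-fold lower, from 37.3 ± 2.16 to 4.45 ± 0.596 CPM (log2 fold change -3.06 ± 0.10, adjusted p = 1.00e-15). DCN, the matrix proteoglycan decorin, was 36.1-fold higher, from 3.03 ± 0.197 to 109 ± 2.24 CPM (log2 fold change 5.17 ± 0.08, adjusted p = 6.68e-21), and FN1 was 25.8-fold higher, from 61.7 ± 5.04 to 1589 ± 191 CPM (log2 fold change 4.69 ± 0.10, adjusted p = 1.40e-18). MKI67 was lower in p21 by a further 3.0-fold (log2 fold change -1.59 ± 0.11, adjusted p = 2.51e-10), as were LMNB1 (-1.30 ± 0.20), BRCA1 (-0.64 ± 0.09) and BRCA2 (-1.08 ± 0.18).

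The edgeR test called 3944 genes higher and 3938 lower in p21 than in p16, with 887 and 743 changed by 2-fold or more. Besides DCN, the largest excesses in p21 within these limits were in HSPB7, a small heat shock protein, ABCA8 (5.65 ± 0.12), the channel AQP9 (5.37 ± 0.22) and the actin-bundling protein LCP1 (5.30 ± 0.08). HSPB7 had 240 counts in p21 against 2 in p16, a ratio of 121 (95% exact interval 33.2 to 1008). The most depleted in p21 were S100A7, SERPINB13, S100A8 (-6.92 ± 0.13), SLC6A14 (-6.28 ± 0.19) and the cadherin FAT2 (-5.89 ± 0.18). S100A7 had 1 count in p21 against 287, a ratio of p16 to p21 of 284 (95% exact interval 50.5 to 11251), and SERPINB13 had 3 against 492, a ratio of 162 (95% exact interval 55.2 to 789). Their fitted values were -9.61 without p21 replicate 3 and -7.99 without p21 replicate 2, against -7.70 and -7.18 with all libraries.

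The cell cycle and homologous recombination lists were lower in p21. In G2 and mitosis, 45 of 54 tested members were lower and 1 higher (median log2 fold change -1.09, adjusted p = 1.23e-12; 1 up and 46 down adjusted over the list alone). CDC20 (-2.64 ± 0.16) was among the lowest and BUB3 (0.42 ± 0.04) was higher. DLGAP5 (-2.79) was -4.11 without p21 replicate 3. In DNA replication, 32 of 50 tested members were lower and 4 higher (median log2 fold change -0.48, adjusted p = 3.76e-05; 4 up and 33 down adjusted over the list alone). MCM10 (-2.21 ± 0.34) was lowest, PCNA (0.42 ± 0.07) was higher, and TYMS (1.23) is overlapped over 46.6% of its exonic bases. In homologous recombination and Fanconi anaemia, 17 of 43 tested members were lower and 4 higher (median log2 fold change -0.22, adjusted p = 0.00676). BLM (-1.44 ± 0.31) was lowest and MUS81 (0.37 ± 0.09) and FANCL (0.35 ± 0.10) were higher. The end joining list did not pass (2 up and 7 down of 19, median -0.11, adjusted p = 0.517), and its members MAD2L2 (0.60 ± 0.09) and TP53BP1 (0.54 ± 0.05) were higher and POLQ (-1.06 ± 0.23) and XRCC6 (-0.18 ± 0.03) lower.

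The p53, ATF4 and autophagy lists were higher in p21. Among p53 targets, 25 of 35 tested members were higher and 3 lower (median log2 fold change 0.33, adjusted p = 6.70e-05; 26 up and 3 down adjusted over the list alone). EDA2R (1.43 ± 0.09) and GDF15 (1.39 ± 0.10) were highest and PERP (-1.50 ± 0.04) was lowest. Among ATF4 targets, 24 of 36 tested members were higher and 5 lower (median log2 fold change 0.38, adjusted p = 3.05e-06; 25 up and 5 down adjusted over the list alone). PHGDH, the first enzyme of serine synthesis, was highest (4.18 ± 0.19), while DDIT4 (-0.37 ± 0.08), overlapped over 41.2% of its exonic bases, was lower. Among FOXO targets, 17 of 31 tested members were higher and 4 lower (median log2 fold change 0.23, adjusted p = 0.0127, but adjusted p = 0.0893 with an estimated correlation (0.00109 to 0.0893 over 11 alternatives); 18 up and 5 down adjusted over the list alone). TSC22D3 (1.54 ± 0.05) was highest and the receptor ERBB3 (-1.66 ± 0.05) was lowest. In autophagy, 16 of 44 tested members were higher and 5 lower (median log2 fold change 0.10, adjusted p = 0.0268). MAP1LC3A (1.13 ± 0.14) and GABARAPL1 (0.95 ± 0.05) were highest. In immediate early and heat shock genes, 15 of 25 tested members were lower and 4 higher (median log2 fold change -0.35, adjusted p = 0.00111). DUSP1 (0.62 ± 0.03) was higher and NR4A1 (-1.84 ± 0.16) lower, and DUSP6 (-2.13) is overlapped over 40.5% of its exonic bases.

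The cholesterol, translation, oxidative phosphorylation and luminal lists were lower in p21 than p16, but only cholesterol fell against mVenus. In cholesterol synthesis, 21 of 24 tested members were lower and 1 higher (median log2 fold change -1.10, adjusted p = 1.89e-10). HMGCS1 (-1.80 ± 0.06) and MVD (-1.67 ± 0.06) were lowest and PMVK (0.31 ± 0.07) was higher. In fatty acid synthesis, 9 of 16 tested members were lower and 6 higher (median log2 fold change -0.43, adjusted p = 0.0223, but adjusted p = 0.0544 with an estimated correlation (0.00210 to 0.0544 over 11 alternatives)). SCD (-2.57 ± 0.04) was lowest and FADS1 (0.84 ± 0.11) was highest. Among cytosolic ribosomal proteins, 71 of 74 tested members were lower and 0 higher (median log2 fold change -0.42, adjusted p = 4.20e-21). RPL24 (-0.63 ± 0.04) was among the lowest. In ribosome biogenesis, 28 of 49 tested members were lower and 2 higher (median log2 fold change -0.17, adjusted p = 0.000514; 2 up and 29 down adjusted over the list alone). TCOF1 (-0.86 ± 0.05) was lowest. In nuclear-encoded oxidative phosphorylation, 37 of 50 tested members were lower and 1 higher (median log2 fold change -0.27, adjusted p = 1.50e-07; 2 up and 38 down adjusted over the list alone). COX7A2 (-0.43 ± 0.05) was lowest. NDUFA4 (0.10 ± 0.04) of this list was higher, but was not called without p16 replicate 3, without any 1 of the p21 replicates, without the low-count filter, with DESeq2 size factors or by DESeq2 (adjusted p 0.0557 to 0.224, 0.0202 to 0.224 over 11 alternatives). In keratinising differentiation, 17 of 22 tested members were lower and 3 higher (median log2 fold change -1.91, adjusted p = 1.67e-07, but adjusted p = 0.0661 with an estimated correlation (5.74e-12 to 0.0661 over 11 alternatives)). CRCT1 (1.39 ± 0.17) and KLK7 (1.24 ± 0.07) were higher. In basal mammary epithelium, 11 of 22 tested members were lower and 4 higher (median log2 fold change -0.33, adjusted p = 0.00863, but adjusted p = 0.0544 with an estimated correlation (0.000521 to 0.0544 over 11 alternatives)). MYLK (1.11 ± 0.19) was higher. In luminal mammary epithelium, 12 of 14 tested members were lower and 1 higher (median log2 fold change -0.79, adjusted p = 3.93e-05). KRT7 (0.41 ± 0.04) was higher. KRT19 had 3 counts in p21 against 70, a ratio of p16 to p21 of 23.1 (95% exact interval 7.58 to 115), fitted at -4.37 and at -5.20 without p21 replicate 3. In the mesenchymal and fibroblast list, 16 of 20 tested members were higher and 0 lower (median log2 fold change 1.55, adjusted p = 8.86e-09). Of the endothelial markers, ROBO4 (-4.36 ± 0.19), PECAM1 (-2.19 ± 0.34) and KDR (-1.17 ± 0.24) were lower in p21, and of the leukocyte markers CD14 (-0.72 ± 0.09) was lower while CSF1R (0.09 ± 0.05) and ITGAX (-1.25 ± 0.76) did not pass.

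Lists without a call between p21 and p16 were interferon-stimulated genes (13 up and 14 down of 43, median 0.02, adjusted p = 0.969, 14 and 14 adjusted over the list alone), lysosome (25 up and 13 down of 53, median 0.12, adjusted p = 0.0501, 25 and 14 adjusted over the list alone), secretory factors of senescence (21 up and 16 down of 41, median 0.40, adjusted p = 0.195), NF-kappaB targets (12 up and 6 down of 26, median 0.06, adjusted p = 0.507), nuclear architecture in senescence (2 up and 12 down of 25, median -0.13, adjusted p = 0.0550) and glycolysis and hypoxia (7 up and 16 down of 29, median -0.18, adjusted p = 0.0733). The same held for mismatch repair (4 up and 9 down of 20, median -0.18, adjusted p = 0.484), base excision repair (6 up and 7 down of 23, median -0.02, adjusted p = 0.825), nucleotide excision repair (8 up and 7 down of 22, median 0.02, adjusted p = 0.958), DNA damage signalling (5 up and 5 down of 31, median -0.04, adjusted p = 0.995), mitochondrially encoded mRNAs (4 up and 1 down of 13, median 0.08, adjusted p = 0.507) and E2F and cyclin-dependent kinase regulators (8 up and 4 down of 26, median 0.07, adjusted p = 0.514). The lysosome list passed without p16 replicate 1 or p21 replicates 1 or 2 (adjusted p 0.0392 to 0.0410, 0.0161 to 0.309 over 11 alternatives), the nuclear architecture list without p16 replicate 1 or p21 replicates 1 or 3 (0.0358 to 0.040, 0.00745 to 0.212 over 11 alternatives), and the glycolysis list without p16 replicate 3 (0.0437, 0.0128 to 0.309 over 11 alternatives). Without the low-count filter these 3 lists passed as well (0.0161, 0.00745 and 0.0128). Of secretory genes, TGFB2 (4.73 ± 0.17) and IGFBP4 (4.02 ± 0.28) were higher, CXCL8 was 4.98-fold lower, from 67.4 ± 3.79 to 13.4 ± 2.14 CPM (log2 fold change -2.32 ± 0.09, adjusted p = 2.01e-14), and MMP9 and INHBA, with 0 counts in p21, were at least 2.32-fold and at least 2.02-fold lower. With both at these bounds the median of the secretory list stayed at 0.40, and the INHBA call ended without p16 replicate 3 (adjusted p = 0.101, 0.00733 to 0.101 over 10 alternatives). Of lysosomal genes, FUCA1 (1.94 ± 0.05) and ARSB (1.15 ± 0.08) were higher and TCIRG1 (-1.26 ± 0.08) lower, and GLB1 did not pass (log2 fold change -0.05 ± 0.05, adjusted p = 0.418). For the interferon, nucleotide excision repair and damage signalling lists the median and mean differed in sign.

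Of the 30 lists, 17 passed camera with the preset correlation and 13 with an estimated one. As p21 and p16 cells are different lines, this contrast holds any difference between the lines too.

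**Figure D3:**
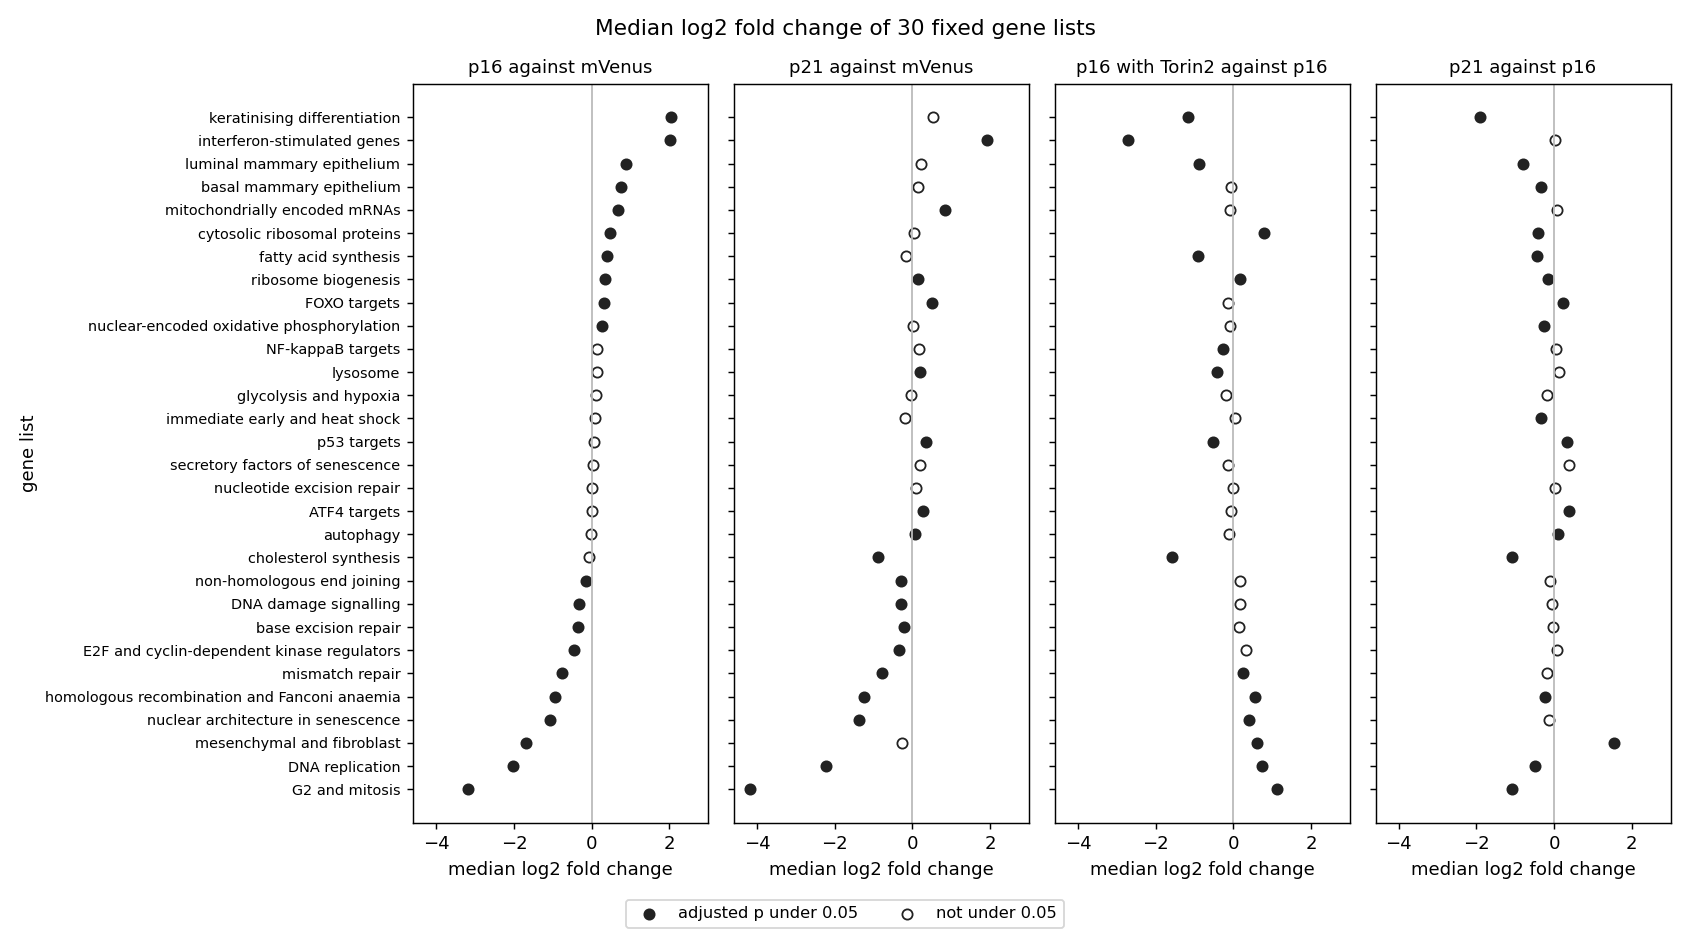
Each point is the median log2 fold change of a fixed gene list, named on the vertical axis, over its tested members in 1 of the 4 comparisons (panels), filled where camera with a preset correlation gave an adjusted p under 0.05. G2 and mitosis (-3.18, -4.19, 1.12 and -1.09 from left to right) and interferon-stimulated genes (2.02, 1.93, -2.71 and 0.02) had among the widest spans.

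Changes in p16 and p21 were set against each other gene by gene. Of genes called in both comparisons against mVenus, 5377 changed in the same direction and 962 in opposite directions, where independent lists of these sizes would give 2607 each. MKI67, LMNB1, BRCA1, BRCA2, MYH14 and TLR2 fell in both, IFIT1 and CITED2 rose in both, and CDKN1A moved apart, down in p16 and up in p21. The log2 fold changes correlated across genes with r = 0.612. Simulated unchanged groups that share the mVenus libraries gave a mean r of 0.480 over 20 simulations and 0.05 genes called in the same direction. The covariance was 0.533 against 0.0246 in the simulations. Genes are not independent replicates, and part of the excess may come from the shared mVenus libraries, which are too few to be split.

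Changes with Torin2 were set against those of p16 in the same way. Of genes called in both, 4278 changed in opposite directions, 2179 of them up in p16 and down with Torin2 and 2099 the reverse, and 1926 changed in the same direction. Independent lists would give 2743 and 2740. MKI67, LMNB1, BRCA1 and FN1 fell in p16 and rose with Torin2, and CXCL8, GLB1 and TRIM22 did the reverse. The ribosomal protein list rose and CDKN1A fell in both. The correlation of log2 fold changes was -0.471, and simulated unchanged groups that share the p16 libraries gave -0.513. The covariance was -0.362 against -0.0269 in the simulations, which called 0.05 genes in opposite directions on average. Shared p16 libraries favour opposite directions to an unknown extent, so these counts cannot show how far Torin2 opposed p16.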

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

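Tests on length and expression matching and on pseudogene counts were written before their results were seen; all other tests of explanations here, and the splits of the libraries, were chosen afterwards.

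For 17 gene lists the change against mVenus differed between p21 and p16, as tested by the direct contrast of p21 against p16 with camera. With an estimated correlation 13 did, and not FOXO targets (adjusted p = 0.0893), fatty acid synthesis (0.0544), basal (0.0544) or keratinising (0.0661), each the highest of its 11 alternatives. The median log2 difference, p21 minus p16, was -0.48 for DNA replication, -1.09 for G2 and mitosis and -0.22 for homologous recombination. For stress lists it was 0.33 (p53 targets), 0.38 (ATF4 targets), 0.23 (FOXO targets), 0.10 (autophagy) and -0.35 (immediate early genes). For metabolism and translation it was -1.10 (cholesterol synthesis), -0.43 (fatty acid synthesis), -0.27 (oxidative phosphorylation), -0.42 (ribosomal proteins) and -0.17 (ribosome biogenesis). For cell identity it was -0.33 (basal), -0.79 (luminal), -1.91 (keratinising) and 1.55 (mesenchymal).

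Interferon-stimulated genes were higher in p16 and p21 than in mVenus and lower with Torin2 by camera, but not with an estimated correlation (adjusted p = 0.105, 0.0936 and 0.0672, each the highest of 11 alternatives). RNA from leukocytes is argued against, as PTPRC, LYZ and TYROBP, abundant in such cells, summed to at most 0.0212 CPM in p16 and p21, although 34.0% of the exonic bases of LYZ are shared with another gene. A first measure, the summed leukocyte list over the summed interferon list (0.995% in p16), rested on CSF1R and CD14 and came too near its bound to decide, so it was replaced. List medians were at least 1.93 above that of the other tested genes. A scaling factor cancels in this difference, so scaling was not tested (medians under 3 scalings, used first, were replaced, as these differ little). A difference between the cell lines cannot be told apart from induction, because line and transgene coincide (the lower median is 1.93), whereas the fall of the same list with Torin2 (median -2.71) lies within 1 line.

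Ribosomal protein mRNAs were higher with Torin2 (list median 0.78). Of 1000 lists matched on exonic length and mean expression the highest median was -0.0144, which argues against short or abundant transcripts as the source. Of 119 tested ribosomal protein pseudogenes 80 rose and 1 fell (median 0.80), which argues against reads moved from them to the parent genes. The list median was 0.76 above that of the other tested genes, where scaling cancels as above, so the rise is only relative to them. The rise may be a response to Torin2, a hypothesis found and tested on the same libraries.

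The mesenchymal list was higher in p21 than p16, but not mVenus (summed CPM 2216, 256 and 3203). Fibroblast RNA is argued against, as COL1A1, COL1A2 and COL3A1 summed to 3.86 CPM in p21 beside 109 CPM of DCN. Line and induction (median 1.55) cannot be told apart without uninduced libraries. Whole-chromosome gain or loss (0.585 for 3 copies over 2) is argued against, as the largest absolute chromosome median between lines was 0.0824.

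Splits of a comparison's 6 libraries into 3 and 3 number 10, too few for a share under 0.05. All but the real one mix the groups, so their calls do not measure chance. The real split called 9238 genes in p16, 8187 in p21, 8608 with Torin2 and 7882 between p21 and p16. The highest other split called 0, 0, 1 and 0, so 1 of 10 gave as many. For lists the real values were 20, 18, 16 and 17 and the highest others 17, 15, 17 and 15. As many lists came from 3 of 10 splits with Torin2 and from 1 of 10 otherwise.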

How the results depend on the processing

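The alternatives without overlapped genes, with p16 replicate 3 and Torin2 replicate 3 both left out, and with scaling that ignores ribosomal protein and mitochondrial genes were chosen after seeing the data. The pair had no measured reason, and distances between replicates (0.252 to 0.307 on the log2 scale) later set no library apart. Of the named-gene values under the other alternatives, 3923 kept their direction and side of the threshold, 67 were no longer called, 1 (TP53BP1 in p21 without the low-count filter) was newly called and 0 changed direction. The correlation of p16 and p21 fold changes was 0.543 without the low-count filter, against 0.612. Lists called in p16 numbered 13 with an estimated correlation, against 20, and those with Torin2 numbered 28 by fry, against 16, as fry tests the list alone. All other counts of genes and lists stayed within 1.5 times their value. Over all alternatives, genes higher ranged from 4125 to 5149 in p16, 3741 to 4648 in p21, 3789 to 4786 with Torin2 and 3466 to 4015 between p21 and p16, and genes lower from 4189 to 4806, 3571 to 4335, 3843 to 4515 and 3532 to 4076. With any 1 library left out, genes higher ranged from 4130 to 4370, 3741 to 3897, 4042 to 4363 and 3673 to 3840, genes lower from 4435 to 4683, 3765 to 3909, 3954 to 4174 and 3532 to 3840, and lists from 19 to 20, 17 to 18, 16 to 17 and 17 to 19, in the same order. Genes shared by p16 and p21 then ranged from 4815 to 5457, genes opposed by Torin2 from 3937 to 4235, the correlation of p16 and p21 from 0.602 to 0.618 and that of p16 and Torin2 from -0.482 to -0.453. Without 1 library the log2 fold change of CDKN1A ranged from -0.34 to -0.28 in p16, 0.31 to 0.34 in p21, -1.18 to -1.08 with Torin2 and 0.60 to 0.66 between p21 and p16.

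Replicate numbers did not pair the libraries. Deviations from group means correlated at -0.0822 to 0.0754 over the 18 pairs with the same number and at -0.0959 to 0.138 over the others, and 6 of 12 libraries were closest to their own number. With a replicate block 9115, 8073, 8505 and 7742 genes were called in p16, p21, Torin2 and p21 against p16, of which 9068, 8006, 8447 and 7692 were shared with the fit without it. Under the block the calls of the fatty acid list in p16 (adjusted p = 0.0585), the autophagy list in p21 (0.0512), MRE11 in p16, SQSTM1 in p21 and NDUFA4 between p21 and p16 were lost, with no other named gene or list call changed. The cause of these changes was not tested. Depth limits genes under the floor of 3 counts and fold changes against groups at or near 0 counts.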

Other observations

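All tests in this part were chosen after the data were seen, on 173 groups of at least 10 tested genes that share the start of their symbol. Medians are of log2 fold changes, and adjusted p values are by camera, first as preset and then with an estimated correlation. Histone genes moved with Torin2. Of 27 tested HIST genes, 2 are pseudogenes and others encode core and linker histones. Of the 27, 0 rose and 24 fell (median -1.52, adjusted p = 1.6e-09 and 0.0124). HIST1H1C, a linker histone, fell from 101 ± 5.43 to 24.3 ± 2.15 CPM (-2.05 ± 0.06) and HIST2H2BE from 55.6 ± 1.76 to 19.3 ± 1.82 CPM (-1.52 ± 0.07). Against mVenus, 21 rose and 1 fell in p16 (median 0.92, adjusted p = 4.13e-05 and 0.0761), and 19 rose and 1 fell in p21 (median 0.76, adjusted p = 7.98e-05 and 0.105). Libraries were made from polyadenylated RNA, and most histone mRNAs of dividing cells lack a poly(A) tail. No test addressed whether tail or transcript level changed.

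Of 54 tested KRT genes, 30 are pseudogenes, 25 of them copies of KRT8 or KRT18, which can share reads with these. Of the 54, 43 rose and 4 fell in p16 (median 1.04, adjusted p = 5.96e-06 and 0.236), 0 rose and 45 fell with Torin2 (median -1.09, adjusted p = 1.05e-08 and 0.149), and 3 were higher and 30 lower in p21 than in p16 (median -0.57, adjusted p = 0.000247 and 0.465). Of the 24 that are not pseudogenes, 18 rose and 3 fell in p16 and 0 rose and 19 fell with Torin2, and 3 were higher and 15 lower in p21 than in p16. Of 33 EEF genes, 21 are pseudogenes, which can share reads with their parents, and others are elongation factors and enzymes that modify them. Of the 33, 23 rose and 1 fell with Torin2 (median 0.94, adjusted p = 0.000207 and 0.103), EEF1A1 from 4277 ± 31.7 to 8932 ± 92.6 CPM (1.06 ± 0.03) and EEF2 from 3438 ± 173 to 7176 ± 171 CPM (1.06 ± 0.04). Of the EEF pseudogenes 19 rose and 0 fell (median 1.03), and of the 12 others 4 rose and 1 fell (median 0.29). Of 20 SNHG genes, the host genes of small nucleolar RNAs, 15 rose and 1 fell with Torin2 (median 0.61, adjusted p = 0.00230 and 0.202).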
